A study of Mus musculus with 2 samples.

How the data were processed

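The data are one-colour Cy3 expression arrays of total RNA from isolated mouse pancreatic islets. Per the labels, islets came from C57BL/6J mice 8 weeks of age, 3 days after removal of 60% of the pancreas (pancreatectomy) or after a sham operation. The series holds 2 samples, and each is described as replicates on 4 arrays, so the comparison is of 4 pancreatectomy arrays with 4 sham arrays. Nothing in the labels says that the 4 arrays of a group came from separate animals or separate islet preparations, so p-values measure only the spread between these arrays, which may be technical in part. Liver, gut and B-cell transcripts differed between arrays of a group, as given below, so these arrays did not all carry the same RNA. At which step this arose is not known. All 8 arrays lie on 1 slide. Sham arrays fill slide columns 1 and 2 and pancreatectomy arrays columns 3 and 4, so column and group cannot be told apart. Each of the 2 slide rows holds both groups.

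The deposited scanner output gives each spot's intensity on a linear scale, made with Feature Extraction 10.7.3.1 per the file headers, while the submitters' processing notes name version 9.1. Per the file headers the processed signal is background-subtracted and detrended within each array, with no scaling between arrays. Flags that mark spots well above background, saturated spots, and non-uniform or population outlier spots were set by the same software, per the file headers. The authors' deposited table of the whole series holds 1 average per group of the raw intensity and of a log2 value, processed with GeneSpring GX 12.5 and a 75th percentile shift, per the file headers. Its normalized columns have medians of 0.0714 for sham and 0.0033 for pancreatectomy, as they would after a centring step, while single probes lie further from 0. Set against the array values over 37490 kept probes, its pancreatectomy minus sham differences had a slope of 0.999 and r of 0.985 across probes, which sets the base of its log at 2 and its direction as pancreatectomy minus sham. The table gives no value per array, so it served for gene names and as a check of differences, and gave no test.

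Each array had 59305 spots after control spots were left out, for 55681 probes. Non-uniform and population outlier spots were left out, from 113 to 228 per array, and no spot was saturated. The main values are log2 of the processed signal minus each array's 75th percentile of it, with the mean of the 8 percentiles added back. Spots of 1 probe were averaged. A probe was kept if it was well above background on at least 4 of the 8 arrays and had at least 3 values in each group. A gene is represented by its brightest kept probe, by mean over the 8 arrays. Where probes of a named gene differ in direction, the text says so. Symbols come from the authors' deposited table and were updated through its Entrez IDs with a table of the GRCm38 assembly, used for names only. Of 33325 probes with a symbol, 30994 were matched in this way, 3525 symbols changed, and 2331 were kept as given. The other 22356 probes have no symbol there and are tested by probe. This left 30864 features, 18641 with a symbol and 12223 without. Probe positions are those of the array design on the mm9 build, per the file headers. Exon and UTR annotation on that build was not used here.

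Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the 30864 features and a threshold of 0.05 on the adjusted p. Log2 fold changes are pancreatectomy minus sham and are followed by their standard error (SE). Levels are means of normalized log2 signal ± SD over 4 arrays. Where a gene was not well above background on any array of a group, its change is given as at least N-fold. This sets the mean of the bright group against the mean, over the dim arrays, of the higher of the lowest signal well above background and the probe's own signal. The number of arrays limits the precision of every value, and the median SE over all features was 0.22. On simulated data with the means and spreads of these arrays and 200 changed genes among 30767, limma recovered 34.3% of changes of 1 on the log2 scale, 85.1% of changes of 2 and 100% of changes of 3, with 5 false calls. The noise was independent for each gene and was added after filtering and scaling. The simulation thus leaves out genes that vary together, and its false calls need not hold for these arrays.

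Gene lists, numbering 35, were fixed before the data were examined. They cover beta-cell identity, stimulus-secretion coupling, other islet hormone cells, DNA replication and S phase, mitosis and G2/M, G1 cyclins and CDK inhibitors, insulin and IGF signalling, the unfolded protein response, the Reg family, markers of acinar, duct, macrophage, lymphocyte, neutrophil, endothelial, fibroblast (with stellate and pericyte), Schwann, adipocyte and erythroid cells, extracellular matrix remodelling, inflammatory cytokines and chemokines, the interferon response, immediate-early genes, heat shock proteins, prolactin and serotonin genes, glycolysis, the hypoxia response, oxidative phosphorylation with the TCA cycle, beta-cell disallowed genes, endocrine progenitor and dedifferentiation genes, cholesterol synthesis, p53 targets, antioxidant and metallothionein genes, growth factors and receptors, and ribosomal proteins. Lists with at least 5 measured members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over 34 lists, then again with an estimated correlation, and with fry of limma. For each array a list's mean was taken relative to the mean of the sham arrays.

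Named genes followed a rule fixed with the lists. It takes the 10 largest rises and the 10 largest falls with a gene symbol (not an accession, clone, Gm, LOC or Rik name) among features past the threshold whose groups do not overlap, up to 4 members past the threshold from each list past the camera threshold and up to 2 from each other list, and 16 fixed genes. Genes that passed adjusted over their list alone, stood apart on 1 array or turned sign are named too, and other genes are said to be chosen or named after their values were seen. Results for a few single genes, and tests that used them, are not reported here. Single array measures were compared with exact two-sided permutation tests, for which 4 arrays against 4 can give no p below 0.0286.

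Alternatives were normexp background correction, quantile, median and no scaling, no filter and a stricter filter on dim probes, the mean of a gene's probes, every probe on its own, outlier spots kept, an intensity trend with robust variances, array weights, the slide row as a block, and leaving out each array in turn. Normexp used the median spot signal with the median local background and an offset of 50, since the mean spot signal was not used here. Leaving out pancreatectomy replicates 1 and 3 together, quantile scaling without sham replicate 3, and leaving out the 4 arrays with liver, gut or B-cell transcripts were added after seeing the data. The last sets 3 sham arrays against 1 on the same features, and the lone array is assumed to vary like the sham arrays. The list test was not run there.

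Lists of liver, gut and B-cell genes were written after single genes of these tissues had been seen at high levels. The genes not looked at before, 13, 11 and 7 of them measured, were kept as separate lists and are the ones given in the comparison. For each array the median difference of a list from the mean of sham replicates 1, 2 and 3 was taken. These lists were not tested with camera, and none of their genes passed the threshold.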

Results

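Transcripts were measured in isolated islets of 8-week-old C57BL/6J mice on 8 one-colour arrays, 4 from islets taken 3 days after removal of 60% of the pancreas and 4 from islets taken after a sham operation. The 75th percentile of the processed signal was 559, 548, 178 and 655 on sham replicates 1 to 4 and 640, 280, 525 and 376 on pancreatectomy replicates 1 to 4. The share of probes well above background was 64.5% ± 11.0 (SD, n = 4) on sham arrays and 65.2% ± 5.41 on pancreatectomy arrays, and sham replicate 3 was lowest at 48.1%. Across genes, which are not independent replicates, pairs of arrays within a group correlated with r from 0.960 to 0.993 and pairs between groups with r from 0.949 to 0.987.

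Some arrays also carried transcripts of liver, gut and B cells, which were looked for only after the values were seen. Albumin (Alb) had a normalized log2 signal of 13.8 on sham replicate 4, 14.9 on pancreatectomy replicate 1 and 12.6 on pancreatectomy replicate 4, against 2.11 to 4.90 on the other 5 arrays. Over 13 further liver genes that had not been looked at before, the median log2 difference from the mean of sham replicates 1, 2 and 3 was 2.81, 2.63 and 1.88 on those 3 arrays and at most 0.19 on the others. Pancreatectomy replicate 3 carried gut and B-cell transcripts, with a median difference of 1.96 over 11 further gut genes and 3.03 over 7 further B-cell and plasma cell genes, against at most 0.25 on any other array. Sham replicates 1, 2 and 3 are the reference for these differences, with Alb at 3.99 to 4.90, and pancreatectomy replicate 2 lay near them, with Alb at 2.11. Arrays near the reference are called without these transcripts below, although low levels cannot be excluded.

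**Figure D1:**
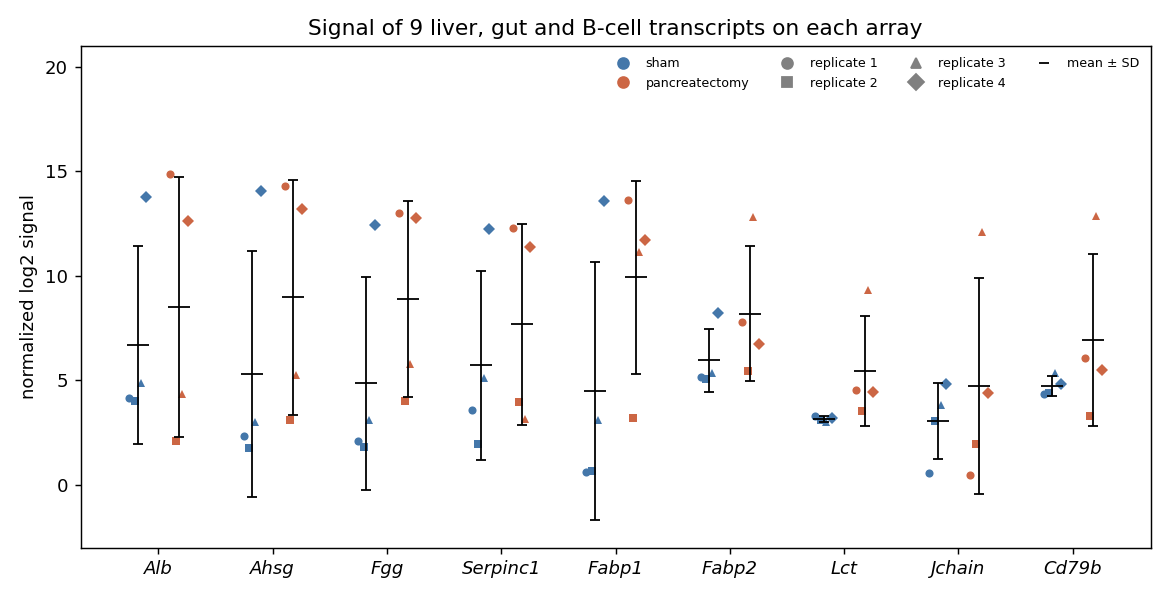
Normalized log2 signal of 9 transcripts of liver (Alb, Ahsg, Fgg, Serpinc1), of liver and gut (Fabp1), of gut (Fabp2, Lct) and of B cells (Jchain, Cd79b) on each array, with the mean ± SD of each group's 4 arrays. Alb reached 13.8 on sham replicate 4 and 14.9 on pancreatectomy replicate 1, and Cd79b reached 12.8 on pancreatectomy replicate 3.

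The comparison of pancreatectomy with sham arrays addresses which islet transcripts differ 3 days after most of the pancreas was removed. Transcripts of DNA replication and cell division rose after pancreatectomy, with 17 of 32 and 25 of 34 measured list members past the threshold. Mki67, which marks cycling cells, rose 15.1-fold, by 3.91 ± 0.35 on the log2 scale (SE, 4 arrays against 4), and Birc5, which encodes survivin, rose 15.8-fold, by 3.98 ± 0.39. Transcription factors that fell included Tbx1 by 2.95 ± 0.40 and Neurog3, a factor of endocrine progenitors, by 2.11 ± 0.25. The hormone genes did not pass the test, with changes of -0.082 ± 0.34 for Ins1, -0.15 ± 0.39 for Ins2 (0.098 with quantile scaling), -0.50 ± 0.24 for Gcg and -0.15 ± 0.15 for Sst.

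Of 30864 features, 194 passed an adjusted p of 0.05 in limma, 168 higher and 26 lower after pancreatectomy. Of these, 163 rose and 20 fell at least 2-fold. With a gene symbol, 134 rose and 17 fell, and 34 and 9 had none. The median change was 2.90 among features that rose and -1.11 among those that fell, against -0.037 over all features. In all 194 the arrays of the groups did not overlap, which held for 2557 features in all (8.28%, where chance gives 2.86%). Leaving out 1 array left 60 to 160 rises and 4 to 32 falls. Fewer than 100 rose without sham replicate 2 (60, with 4 falls), pancreatectomy replicate 4 (62 and 7), sham replicate 1 (89 and 9) or sham replicate 4 (94 and 6), and 11 and 12 fell without pancreatectomy replicates 1 and 3. With median scaling, which put the median of all features at -0.16, 130 rose and 48 fell, and with no scaling 18 rose and 0 fell, with 388 features at an unadjusted p under 0.05. With normexp 54 rose and 6 fell, and with array weights the balance turned, with 488 higher and 533 lower. With the slide row as a block, 111 rose and 11 fell, and 121 of the 194 features passed again. Within each of the 2 slide rows, 2 arrays against 2, limma called 0 features, with 2021 and 896 at an unadjusted p under 0.05.

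**Figure D2:**
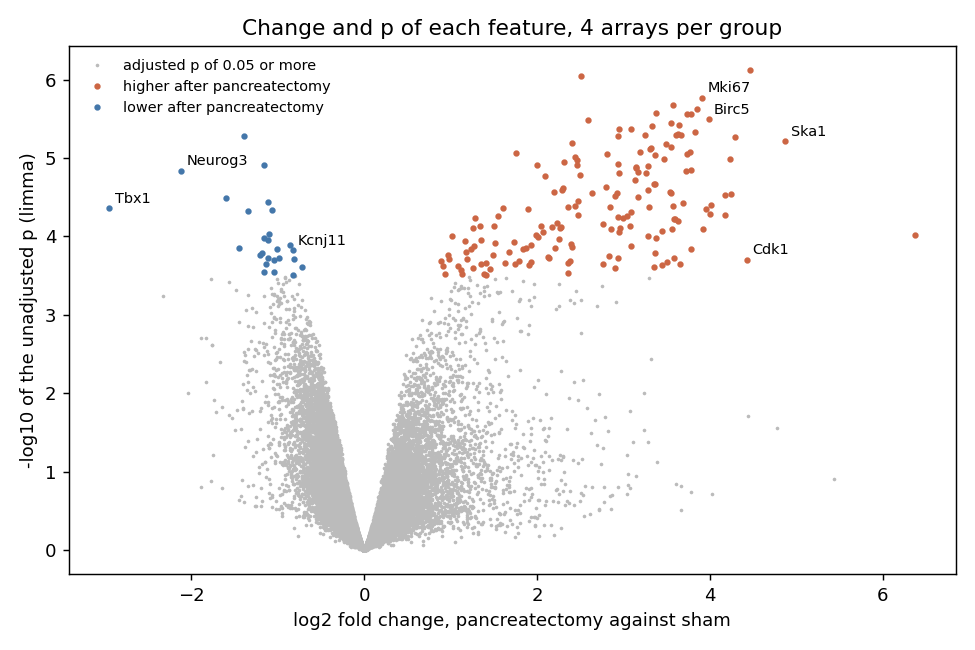
Log2 fold change (pancreatectomy against sham) of each of 30864 features against the -log10 of its unadjusted limma p, with features past the adjusted threshold coloured. The 168 features that rose have a median change of 2.90 and the 26 that fell one of -1.11.

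The cell division list held 34 measured genes of mitosis and G2/M, of which 25 rose, 0 fell and 9 did not pass. Adjusted over the list alone, 32 rose. Its median change was 3.12, and camera of limma gave an adjusted p of 9.3e-59, or adjusted p = 0.143 with an estimated correlation. Cdk1, the mitotic cyclin-dependent kinase, rose by 4.43 ± 0.73, although 1 of its 3 probes gave -0.26. Bub1, a spindle checkpoint kinase, rose by 4.29 ± 0.44, Top2a, a DNA topoisomerase, by 4.18 ± 0.53, and Pbk, a mitotic kinase, by 4.01 ± 0.53. Aurka, a spindle pole kinase, rose by 2.13 ± 0.35 (adjusted p = 0.0365). Foxm1, which drives transcription of G2/M genes, had 1.84 ± 0.33 and did not pass (adjusted p = 0.0558). Its other probe gave 1.11, which passed when every probe was tested on its own. Tpx2, named after its values were seen, had -0.23 by its brightest probe and 3.79 by its other probe. With normexp, Bub1 had 1.69 and lost its call, while Cdk1 (2.86) and Top2a (2.23) kept theirs. As the mean of its probes Cdk1 had 2.61. Aurka lost its call in 15 alternatives, among them the slide row as a block (2.13) and the removal of any 1 array but pancreatectomy replicate 1 or 2. Cdk1 lost it in 15, among them the slide row as a block (4.43) and the removal of any 1 array but sham replicate 3 (changes from 4.04 to 4.85). With quantile scaling Aurka (2.14), Cdk1 (4.46) and Top2a (4.59) lost their calls. Top2a lost its call with no scaling too, and Pbk with no scaling or no filter. Top2a and Pbk also lost theirs without sham replicate 2 (4.22 and 3.82) or pancreatectomy replicate 4 (4.18 and 3.77). Foxm1 passed in 5 alternatives, among them the mean of probes (1.47), array weights (2.00) and the removal of pancreatectomy replicate 1 (1.52).

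The list of DNA replication and S phase held 32 measured genes, of which 17 rose, 0 fell and 15 did not pass. Adjusted over the list alone, 27 rose. Its median change was 1.24, and camera gave an adjusted p of 1.9e-45, or adjusted p = 0.143 with an estimated correlation. Dtl, a substrate adaptor of a ubiquitin ligase in S phase, rose by 4.23 ± 0.47 and Tk1, thymidine kinase, by 3.78 ± 0.60. Uhrf1, which maintains DNA methylation, rose by 3.78 ± 0.36 by its brightest probe and by 0.65 by its other probe, or by 2.21 as the mean of the 2. Cdc6, a replication licensing factor, rose by 3.54 ± 0.45, and lost its call with quantile scaling (3.93), with no scaling (3.53) and without sham replicate 2 (3.52). With normexp, Dtl (1.79) and Cdc6 (1.44) lost theirs. Tk1 lost its call with the slide row as a block (3.78) and without any 1 array but sham replicate 4 or pancreatectomy replicate 2 (changes from 3.43 to 3.90). Its other probe gave 2.41 and did not pass on its own. The list means rose on each pancreatectomy array, from 2.21 to 3.99 for mitosis and from 1.28 to 2.22 for DNA replication, above every sham array (highest 0.33 and 0.20). The lowest pair of values, 2.21 and 1.28, came from pancreatectomy replicate 2, the pancreatectomy array without liver, gut and B-cell transcripts, and sham replicate 4, which carried liver transcripts, had 0.33 and 0.20. The mitosis mean was highest on pancreatectomy replicate 1 (3.99), where the macrophage and fibroblast markers given below were highest too, and it was 2.67 on replicate 3, which also had high markers, and 2.94 on replicate 4, which did not. The erythroid mean lay above every sham array on all 4 pancreatectomy arrays, the Schwann mean on replicates 1, 2 and 4, the neutrophil mean on replicates 1, 3 and 4 and the lymphocyte mean on replicates 3 and 4. With the fibroblast mean, the endothelial mean or the mean of 4 marker lists as a covariate, limma passed 0 of the 42 called genes of these 2 lists, with all 42 at an unadjusted p under 0.05. The median of the members was then 2.09, 2.29 and 2.17, against 2.50 without a covariate. Limma passed 24 of the 42 with the macrophage and 37 with the acinar mean. By slide row, the median changes were 3.50 and 3.09 for mitosis and 1.29 and 1.32 for DNA replication.

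The 10 largest rises by the naming rule, which passes over Rik names, were Ska1, Cdk1, Bub1, Aspm, Dtl, Top2a, Iqgap3, Pbk, Birc5 and Shcbp1, from 3.95 for Shcbp1 to 4.87 ± 0.51 for Ska1, a kinetochore gene (adjusted p = 0.0079). With normexp Ska1 had 2.19 and Shcbp1 2.36 and kept their calls, while Aspm (1.73) and Iqgap3 (1.68) lost theirs. With no filter on dim probes Shcbp1 and Iqgap3 lost their calls. Shcbp1 lost its call without sham replicate 2 (3.78) or pancreatectomy replicate 4 (3.84), and Iqgap3 without sham replicate 3 (4.25) or pancreatectomy replicate 4 (4.15). Ska1, on chromosome 18 (probe at 74356611 to 74356670, mm9), had a level of 8.10 ± 0.63 (SD, n = 4) after pancreatectomy and 3.23 ± 1.03 in sham, where 2 of 4 arrays were above background. Bub1, Aspm, Dtl and Iqgap3 were also above background on 2 of 4 sham arrays, so their rank rests on signal near background. With normexp Bub1 had 1.69 and Dtl 1.79, while Birc5 had at least 3.26 in every alternative, so the order of the 10 is not firm. Chosen after their values were seen, 4 features that rose were above background on no sham array. Among them the rise was at least 3.16-fold for 2700099C18Rik, at least 4.60-fold for probe A_55_P2145136 and at least 6.13-fold for Rad54b.

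**Figure D3:**
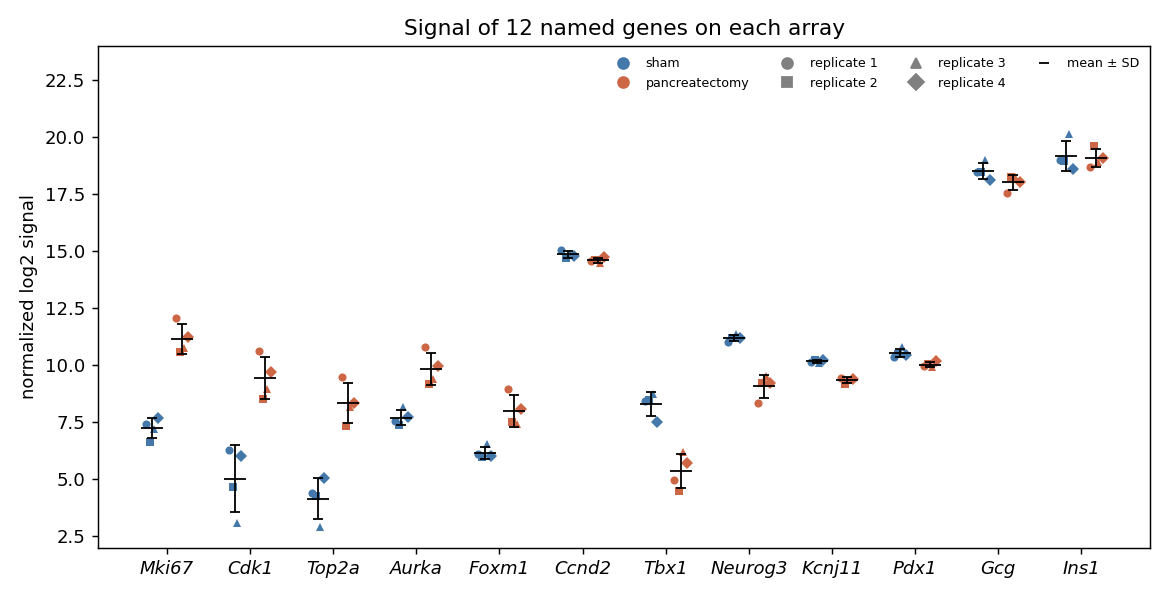
Normalized log2 signal of 12 named genes on each array, with the mean ± SD of each group's 4 arrays. Mki67 lay at 7.23 in sham and 11.1 after pancreatectomy, and Ins1 at 19.2 and 19.1.

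The list of G1 cyclins and CDK inhibitors held 17 measured genes and none passed over all genes; adjusted over the list alone 3 rose (Cdk2, Cdkn2d and Rbl1) and 1 fell (Cdkn2b). Its median was 0.083 (camera adjusted p = 0.0703), and it turned to -0.040 with median scaling. Camera called it without pancreatectomy replicate 2 (0.048). Ccnd1 had 0.20 ± 0.15, Ccnd2, the main cyclin D of islets, -0.26 ± 0.14, and Cdkn1a 0.55 ± 0.44, and none of them passed. Cdkn1a had 0.26 without sham replicate 4 and 0.98 without sham replicate 1.

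The 10 largest falls by the naming rule included Tbx1, Neurog3, Kcnh5, Pdzrn4, Dpp10, Gfra3, Nxph1, T2 and Mapk15, from -2.95 for Tbx1 to -0.99 for Mapk15. Tbx1, on chromosome 16 (probe at 18581807 to 18581866, mm9), fell from a level of 8.29 ± 0.52 (SD, n = 4) to 5.34 ± 0.75 (adjusted p = 0.0161), and its call was lost in 8 alternatives, among them without sham replicate 1 (-2.90), sham replicate 2 (-2.89) or pancreatectomy replicate 4 (-3.06). Neurog3, on chromosome 10 (probe at 61597452 to 61597511), fell from 11.2 ± 0.14 to 9.07 ± 0.51 (adjusted p = 0.0090). Kcnh5 lost its call without sham replicate 1 (-1.53), and Dpp10 without sham replicate 1 (-1.31), sham replicate 2 (-1.40) or pancreatectomy replicate 1 (-1.30). The removal of any 1 array ended the calls of Gfra3 (-1.27 to -1.07) and Nxph1 (-1.19 to -1.02), sham replicate 3 excepted, and of Mapk15 (-1.04 to -0.91), sham replicate 1 excepted. It ended those of Pdzrn4 (-1.50 to -1.32), except for sham replicate 1 and pancreatectomy replicate 2, and of T2 (-1.12 to -1.01), except for sham replicate 1 and pancreatectomy replicate 3. With no scaling Neurog3 did not pass, and with normexp Kcnh5 had -0.66 and did not, while Tbx1 had -1.83 and did. With the slide row as a block Gfra3 (-1.18), Nxph1 (-1.16) and Mapk15 (-0.99) did not pass. The other probe of Pdzrn4 gave -1.39 and did not pass on its own. By slide row the changes were -3.70 and -2.19 for Tbx1 and -2.31 and -1.91 for Neurog3. On pancreatectomy replicate 2 these 2 genes lay 4.04 and 1.95 below the mean of sham replicates 1, 2 and 3.

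The list of other islet hormone cells held 13 measured genes. Of these, 1 fell and 12 did not pass, and adjusted over the list alone 4 fell, Irx1, Irx2 and Fev among them. Its median was -0.33 (camera adjusted p = 0.0151, adjusted p = 0.426 with an estimated correlation), and the call was lost in 5 alternatives, among them quantile scaling and the removal of sham replicate 1 (-0.15) or sham replicate 3 (-0.35). By slide row its median was -0.57 and -0.052. Irx1 and Irx2, alpha-cell transcription factors named after their values were seen, had -1.77 ± 0.31 (adjusted p = 0.0531, and past the threshold without pancreatectomy replicate 3 at -1.98) and -1.35 ± 0.26 (adjusted p = 0.0700). Irx1 also passed with median scaling (-1.89), array weights (-1.64), an intensity trend and the stricter filter (-1.77 in both), and Irx2 with median scaling (-1.47), array weights (-1.26) and an intensity trend (-1.35). Ghrl, Ppy, Pyy and Gc, also named after their values were seen, were positive, from 0.35 to 0.46, with none passing.

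The beta-cell identity list held 22 measured genes, and 0 passed over all genes or adjusted over the list alone, with 20 of 22 changes negative. Its median was -0.37, and camera gave an adjusted p of 8.3e-05, or adjusted p = 0.399 with an estimated correlation. Pdx1, a beta-cell transcription factor, had -0.51 ± 0.15 (adjusted p = 0.275), Mafa -0.36 ± 0.17 and Slc2a2, the glucose transporter of mouse beta cells, -0.64 ± 0.22. With array weights Pdx1 (-0.48) and Slc2a2 (-0.82) passed. The list of stimulus-secretion coupling held 20 measured genes with a median of -0.29 (-0.15 without sham replicate 3), where camera gave an adjusted p of 9.2e-04, or adjusted p = 0.399 with an estimated correlation. Kcnj11, a subunit of the ATP-sensitive potassium channel, fell by 0.83 ± 0.13 (adjusted p = 0.0320), and 19 genes did not pass. Adjusted over the list alone, Kcnj11 alone fell. Its call was lost in 14 alternatives, among them the slide row as a block (-0.83) and the removal of any 1 array but sham replicate 3 (changes from -0.86 to -0.77), and its other probe gave -0.36. By slide row the medians were -0.35 and -0.47 for beta-cell identity and -0.12 and -0.41 for coupling, and Kcnj11 had -0.86 and -0.79. The falls of both lists were larger on pancreatectomy replicates 1 and 3, with means of -0.60 and -0.50 for identity and -0.36 and -0.38 for coupling, than on replicates 2 and 4 (-0.11 and -0.16, and -0.12 and -0.19), where the lowest sham means were -0.12 and -0.22. Without replicates 1 and 3 the medians were -0.11 and -0.16. The beta-cell disallowed list of 18 genes had a median of 0.41 with 0 past (camera adjusted p = 5.5e-04, adjusted p = 0.399 with an estimated correlation). Its highest members, named after their values were seen, were Maf at 1.50, whose other probe gave -0.28, Pdgfra at 1.32 and Ldha at 1.00. Its mean was 1.13 and 0.91 on pancreatectomy replicates 1 and 3 against -0.16 and 0.21 on replicates 2 and 4, and its median turned to -0.028 without replicates 1 and 3.

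Neurog3 was the 1 gene that fell in the list of endocrine progenitor and dedifferentiation genes, where 11 of 12 did not pass and the median was 0.17 (camera adjusted p = 0.611), with 0.026 without sham replicate 4 and 0.31 without pancreatectomy replicate 4. Adjusted over the list alone, Neurog3 fell too. Cck had 1.71 ± 0.62 and Aldh1a3 1.00 ± 0.42, both named after their values were seen. The list of prolactin and serotonin genes had 9 measured genes and a median of 0.13 (camera adjusted p = 0.0596), with 1 rise adjusted over the list alone. Camera called it without sham replicate 3 (0.38) or pancreatectomy replicate 3 (0.19). The gene that rose, Cish, which cytokine signalling induces, had 1.39 ± 0.26 (adjusted p = 0.0659), and passed with the stricter filter, an intensity trend (1.39 in both) and array weights (1.22). The insulin and IGF signalling list of 18 genes had a median of -0.079 (camera adjusted p = 0.611), with -0.18 without pancreatectomy replicate 2 and -0.0099 without replicate 3, and Irs2 had -0.12 ± 0.39.

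Lists of other cell types passed camera while 0 of their genes passed over all genes. Medians were 0.57 over 20 macrophage genes, 0.64 over 13 lymphocyte genes, 0.67 over 9 neutrophil genes, 0.14 over 15 endothelial genes and 0.69 over 17 genes of fibroblasts, stellate cells and pericytes. They were 0.30 over 10 Schwann and glial genes, 0.83 over 7 erythroid genes and 0.32 over 29 acinar genes. Their camera adjusted p ran from 1.2e-06 for fibroblasts to 0.0356 for acinar cells, and with an estimated correlation every one of the 8 lost its call (adjusted p = 0.399 to 0.765 with an estimated correlation). Adjusted over the list alone, 4 erythroid genes (Hba-a1, Hba-a2, Hbb-b1 and Hbb-bs) and 1 Schwann gene (Pmp22) rose, and 0 in the other 6 lists. By its other probe Pmp22 had -0.18. Macrophage, neutrophil, fibroblast and endothelial means were highest on pancreatectomy replicates 1 and 3, lymphocyte (2.98) and acinar (1.39) means on replicate 3, the erythroid mean on replicate 2 (1.08) and the Schwann mean on replicate 4 (0.46). On replicates 1 and 3 the macrophage list means were 1.75 and 1.34 and the fibroblast list means 2.17 and 1.58, against -0.46 and 0.031 on replicate 2, -0.034 and 0.16 on replicate 4, and at most 0.22 and 0.30 in sham. These 2 arrays also had the gut and B-cell transcripts (replicate 3) and liver transcripts (replicate 1) given above. Without these 2 arrays, an alternative added after seeing the data, 55 features rose and 2 fell, the fibroblast median was 0.080 and the macrophage median turned to -0.23, which camera called lower, as it did the interferon list (-0.17). Leaving out 1 array ended the call for macrophages (0.21 without pancreatectomy replicate 1, and 0.91 with the call kept without replicate 2), neutrophils (0.15 without sham replicate 3, 0.51 without pancreatectomy replicate 1) and Schwann cells (0.17 without sham replicate 4, 0.13 without pancreatectomy replicate 4). It also ended that for lymphocytes (0.19 without pancreatectomy replicate 3, and 0.58 to 0.73 without sham replicates 2, 3 or 4) and endothelium (0.12 to 0.17 without sham replicate 4 or pancreatectomy replicates 1 or 3). The lymphocyte median was 1.04 without pancreatectomy replicate 2. The acinar median was 0.66 without sham replicate 1. It was 0.031 without pancreatectomy replicate 3 and turned to -0.24 without sham replicate 3, and both ended its call. By slide row the macrophage medians were 0.67 and 0.47 and the fibroblast medians 0.75 and 0.82. The duct list of 14 genes had a median of 0.19 (camera adjusted p = 0.611), with 0.026 without pancreatectomy replicate 3 and 0.25 without replicate 2. The adipocyte list had 4 measured genes, too few for the list test, with a median of 0.12 and 1 rise, Fabp4, adjusted over the list alone.

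**Figure D4:**
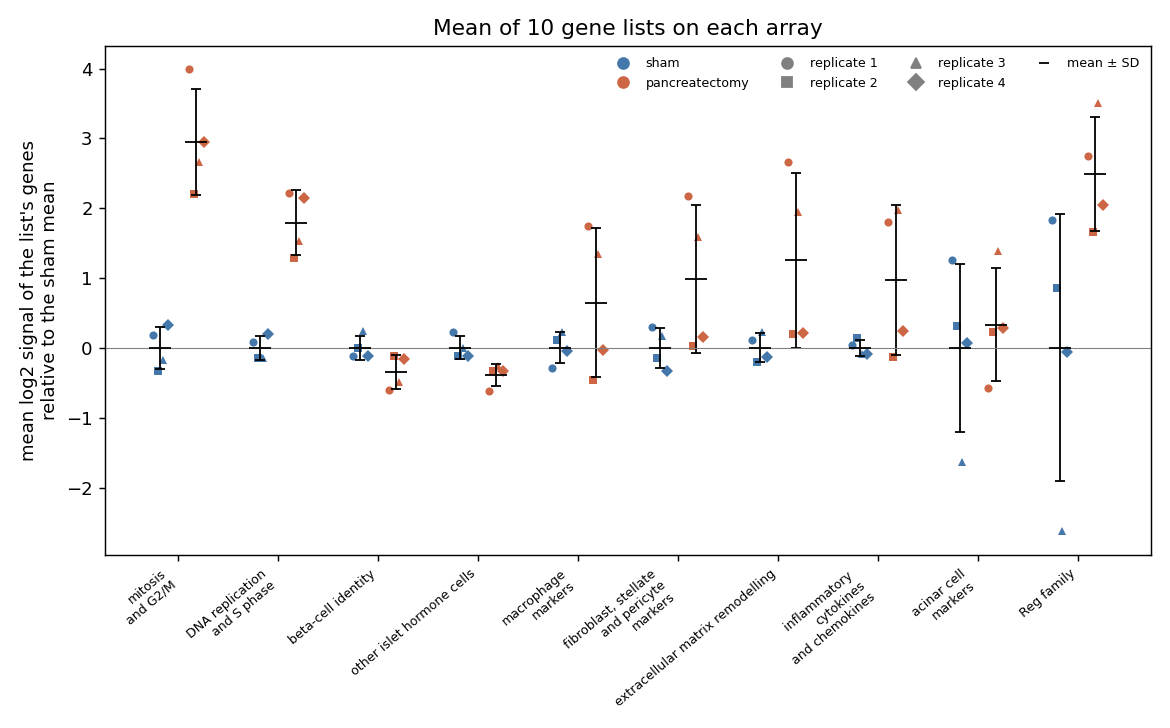
Mean log2 signal of 10 gene lists on each array relative to the sham mean, with the mean ± SD of each group's 4 arrays. The mitosis mean was 2.21 to 3.99 on pancreatectomy arrays, while the fibroblast mean was 2.17 and 1.58 on replicates 1 and 3 and 0.031 and 0.16 on replicates 2 and 4.

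The extracellular matrix list of 16 genes had a median of 1.04 with 0 past (camera adjusted p = 2.5e-06, adjusted p = 0.399 with an estimated correlation), and its mean was 2.66 and 1.94 on pancreatectomy replicates 1 and 3 against 0.19 and 0.21 on replicates 2 and 4. The median was 0.52 without pancreatectomy replicate 1 and 1.59 without replicate 2. Timp1, a metalloproteinase inhibitor named after its values were seen, had 3.24 ± 1.25, with 2.12 without pancreatectomy replicate 1, 4.16 without replicate 4 and 0.72 without replicates 1 and 3. Inflammatory cytokines and chemokines, 17 genes, had a median of 0.62 (camera adjusted p = 8.3e-05, adjusted p = 0.399 with an estimated correlation). Their mean was 1.81 and 1.97 on replicates 1 and 3 against -0.13 and 0.24 on replicates 2 and 4, and the median was 0.33 without replicate 1. Immediate-early genes, 17 in all, had a median of 0.55 (camera adjusted p = 1.3e-05, adjusted p = 0.399 with an estimated correlation), which was 0.33 without sham replicate 4 and 0.34 without pancreatectomy replicate 1. Growth factors and receptors, 20 genes, had a median of 0.21 (camera adjusted p = 0.0163, adjusted p = 0.473 with an estimated correlation), and its call was lost without any 1 of 5 arrays (0.17 to 0.26), while the median was 0.41 without pancreatectomy replicate 4. Without replicates 1 and 3 together, camera called none of these 4 lists, with medians of 0.16 for matrix, 0.19 for inflammatory, 0.24 for immediate-early and -0.048 for growth factor genes. Named after their values were seen, Saa3, an acute-phase gene, had 4.78 ± 1.82, Egr2 2.47 ± 0.78 and Areg 1.85 ± 0.81, and 0 genes of these 4 lists passed over all genes or adjusted over the list alone. Leaving out 1 array, as far as each was still measured, gave 4.15 (without sham replicate 2) to 6.37 (without pancreatectomy replicate 2) for Saa3. It gave 1.94 (without pancreatectomy replicate 3) to 3.00 (without replicate 4) for Egr2 and 1.19 (without sham replicate 4) to 2.36 (without pancreatectomy replicate 4) for Areg. Leaving out 1 array does not show what rests on 2 of them. Saa3 lay at 9.55 and 12.2 on replicates 1 and 3, but at 2.77 and 5.71 on replicates 2 and 4 (highest sham 4.27). Egr2 lay at 8.30 and 8.44 on replicates 1 and 3, but at 5.37 and 5.25 on replicates 2 and 4 (highest sham 5.25). Areg had 5.53 and 4.47, and 5.51 and 3.13 (highest sham 4.69). Saa3 and Areg were above background on only 1 sham array.

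The Reg family, secreted lectin-like proteins of the exocrine pancreas and of stressed islets, had a median of 2.56 over 6 genes (camera adjusted p = 1.9e-05, adjusted p = 0.399 with an estimated correlation). None passed over all genes, and Reg3a, Reg3b, Reg3d and Reg3g rose adjusted over the list alone. The median was 1.62 without sham replicate 3. Named after their values were seen, Reg3g had 3.32 ± 0.85 (adjusted p = 0.198) and Reg3a 3.24 ± 0.99 (adjusted p = 0.302). They had 2.68 and 2.28 without sham replicate 3 and 4.08 and 3.89 without sham replicate 1, and passed with array weights (3.41 and 2.85). By slide row the medians were 0.93 and 4.23, and sham replicate 3 had a list mean of -2.63 against -0.053 to 1.83 on the other sham arrays. The acinar list mean of sham replicate 3 was -1.64 against 0.073 to 1.26 on the others, and Cpa1, a pancreatic carboxypeptidase, had 0.042 ± 0.60, which turned to -0.081 with median scaling.

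In the other lists 0 genes passed over all genes and, with all arrays, camera called none. Medians were 0.17 over 22 genes of the unfolded protein response (adjusted p = 0.0539), 0.043 over 17 interferon response genes (adjusted p = 0.701), -0.17 over 9 heat shock genes (adjusted p = 0.246), -0.077 over 17 cholesterol synthesis genes (adjusted p = 0.611) and 0.067 over 14 p53 targets (adjusted p = 0.246). The interferon median turned to -0.080 with median scaling and -0.023 with quantile scaling, and the p53 median to -0.056 with median scaling. Camera called the unfolded protein list higher without sham replicate 3 (0.24) or pancreatectomy replicate 3 (0.26) and the heat shock list lower without sham replicate 2 (-0.27). The antioxidant and metallothionein list of 16 genes had a median of -0.057 (adjusted p = 0.198), with 5 falls adjusted over the list alone (Gpx3, Gclm, Txnip, Mt1 and Mt2). Mt1 and Mt2, metallothioneins named after their values were seen, had -0.79 ± 0.21 and -0.90 ± 0.17 (adjusted p = 0.0763 for Mt2). Both passed with array weights (-0.59 and -0.77), and Mt2 with an intensity trend (-0.90). Some lists differed in sign between median, mean and test. Over 21 genes of oxidative phosphorylation and the TCA cycle the median was -0.011, the mean 0.0072 and the camera direction up (adjusted p = 0.792), and the median turned to 0.031 with quantile scaling. Over 18 glycolysis genes the median was -0.11, the mean 0.041 and the direction down (adjusted p = 0.843). Over 12 hypoxia genes these were -0.21, 0.12 and down (adjusted p = 0.357), with a median of -0.12 without pancreatectomy replicate 3 and 2 falls adjusted over the list alone (Vegfa and Ndrg1). Over 21 ribosomal protein genes they were -0.018, -0.042 and up (adjusted p = 0.843), and the median turned to 0.0066 with quantile scaling and to 0.053, called by camera, without sham replicate 3.

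Of 34 lists tested, camera with the preset correlation called 16 higher and 3 lower and left 15, and with an estimated correlation it called 0, with the mitosis and DNA replication lists at an unadjusted p under 0.05. Fry gave 8 lists an unadjusted p under 0.05. Leaving out the 4 arrays with liver, gut or B-cell transcripts left 3 sham arrays against pancreatectomy replicate 2. Limma then called 0 features, with 1649 at an unadjusted p under 0.05.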

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

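The test of marker lists that vary together was chosen before its result was seen, and the tests on quantile scaling and on liver transcripts, with the lists of liver, gut and B-cell genes, only afterwards. A sample was singled out where its gap to the nearest of the other 3 arrays of its group exceeded Dixon's 95% critical share of the group's range. That held for 16 of 236 groups of 4 arrays, and chance alone singles out about 1 in 20 groups.

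Sham replicate 3 was the dimmest array, with 48.1% of probes well above background against 68.4% to 70.9% on the other sham arrays, a negative control signal of 33.6 against 22.2 to 23.7 and a spike-in slope of 1.03 against 0.975 to 0.979. It also stood apart in Mafa at 11.88, Aldh1a3 at 8.39 and the oxidative phosphorylation list mean at 0.22. The negative control signal was 25.5 ± 5.48 (SD, n = 4) in sham and 20.1 ± 0.34 after pancreatectomy (exact two-sided permutation p = 0.0286, the smallest 4 arrays against 4 can give, adjusted p = 0.143 over 5 array measures). It alone of the 5 measures reached this p. The difference did not rest on sham replicate 3 alone, as the other sham arrays had 22.2 to 23.7 and the pancreatectomy arrays 19.6 to 20.4. Slide column follows the groups, so a column effect on this signal cannot be told apart from the group. Pancreatectomy replicate 1 stood apart in Mafa at 11.27. Sham replicate 1 stood apart in Il7r at 3.57 and Irx2 at 9.89. Pancreatectomy replicate 2 stood apart in Hba-a2 at 15.4 and the heat shock list mean at 0.040. Pancreatectomy replicate 4 stood apart in the p53 target list mean at 0.012. Pancreatectomy replicate 3 stood apart in Spink1 at 13.7, Cd5 at 7.84, the lymphocyte list mean at 2.98 and the prolactin and serotonin list mean at -0.033.

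At the preset correlation, though for none of the 8 with an estimated one, camera called lists of other cell types higher after pancreatectomy, with macrophage, neutrophil, fibroblast and endothelial means highest on replicates 1 and 3, but lymphocyte and acinar means on replicate 3, erythroid on replicate 2 and Schwann on replicate 4. Quantile scaling turned the sign of 0 of 8 list medians and camera at the preset correlation called all 8 there, although with no scaling the endothelial list (0.14) lost its call. Quantile scaling moved the median of all features only from -0.037 to -0.051, against list medians of 0.14 to 0.83, so it could hardly turn their sign. The calls thus did not depend on this choice, but whether the scaling of the arrays has a part stays open. Within groups, the list means of macrophages, fibroblasts, endothelium and acinar cells had a median pairwise r of 0.43 over 6 pairs. This was short of the 0.5 set beforehand for cells or RNA that vary together between islet preparations. It was above the 0 that would have argued against this explanation. The median describes no single pair. For macrophages with fibroblasts r was 0.92, for fibroblasts with endothelium 0.88 and for macrophages with endothelium 0.69. For acinar cells r was -0.17 with macrophages, -0.057 with fibroblasts and 0.17 with endothelium. No pair passed after adjustment over the 6 pairs (lowest exact permutation adjusted p = 0.0833), so the explanation stays open. Liver transcripts were about as high on sham replicate 4 (a median difference of 8.59 over the 10 genes first seen) and pancreatectomy replicate 4 (8.68) as on pancreatectomy replicate 1 (8.93), yet their macrophage means were -0.038 and -0.034 and their fibroblast means -0.33 and 0.16 against 1.75 and 2.17, which argues against liver RNA as the origin of these 2 on replicate 1. Gut and B-cell transcripts on pancreatectomy replicate 3 (6.25 and 8.14 over the 4 and 3 genes first seen) stayed without a test of where they come from, and whether the marker signals of that array have the same origin was not tested.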

How the results depend on the processing

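Leaving out pancreatectomy replicates 1 and 3, quantile scaling without sham replicate 3, and leaving out the 4 arrays with liver, gut or B-cell transcripts were chosen after seeing the data, and the other alternatives before. The lists of DNA replication and mitosis kept their direction and call in all 21 list alternatives (medians 1.12 to 1.38 and 1.90 to 3.46), as did beta-cell identity (-0.49 to -0.11), stimulus-secretion coupling (-0.41 to -0.15), the Reg family (1.62 to 3.20) and erythroid cells (0.48 to 0.94). The identity median was nearest 0 without pancreatectomy replicates 1 and 3. These calls are camera's at the preset correlation, and with an estimated correlation it called 0 lists, with 2 at an unadjusted p under 0.05. Over these alternatives, which hold neither the fits within 1 slide row nor those with a marker covariate, Mki67 (3.40 to 4.16) and Birc5 (3.26 to 4.26) lost their calls only with 3 sham arrays against 1, and Neurog3 only there and with no scaling. Of the 194 called features, 59 passed again with normexp, 144 with quantile scaling, 156 with median scaling, 18 with no scaling and 185 with the mean of probes. Where arrays were left out their direction was fixed, since their groups do not overlap. The list test was not run without the 4 arrays. With the stricter filter the neutrophil list had too few genes left for the test, and genes dim on some arrays (Cdk1, Bub1, Top2a and Ska1 among them) gave no value there. No paired analysis was possible because nothing in the labels pairs a sham array with a pancreatectomy array, and replicates of the same number sit in different slide columns. A gene dim in sham was above background on few sham arrays, so the size of its rise rests on signal near background and is uncertain. Some named falls also end near background, with levels after pancreatectomy of 3.90 for Nxph1, 4.37 for Kcnh5 and 4.58 for Pdzrn4. The lowest signal well above background was 2.54 to 4.14 on the pancreatectomy arrays. The size of these falls is uncertain too, and with normexp they were -0.37, -0.66 and -0.60. The cause was not tested for any change below, unless the alternative removes arrays, features or probes.

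Counts of genes were 168 higher and 26 lower, and 163 and 20 at 2-fold. They were 54 and 6 with normexp (54 and 6 at 2-fold), 18 and 0 with no scaling (18 and 0), 68 and 4 with no filter (68 and 4), and 488 and 533 with array weights (336 and 101). With the stricter filter 93 rose (89). With the row block 111 rose and 11 fell (11 fell 2-fold), with median scaling 48 fell (38), and with an intensity trend 46 fell. Without pancreatectomy replicates 1 and 3 they were 55 and 2 (55 and 2), with 6 lists higher and 5 lower. Quantile scaling without sham replicate 3 gave 86 rises (82). Without the 4 arrays they were 0 and 0 (0 and 0), with 1649 features at an unadjusted p under 0.05 in limma. Leaving out 1 array gave 60 to 160 and 4 to 32 (60 to 160 and 4 to 23 at 2-fold), lowest without sham replicate 2, and 62 and 7 without pancreatectomy replicate 4, 89 and 9 without sham replicate 1, and 94 and 6 without sham replicate 4.

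List calls that were lost, with the median, were endothelial 0.14 with no scaling and lymphocyte 0.25 with the stricter filter. Array weights lost acinar 0.10, other islet hormone -0.22 and Schwann 0.26. Quantile scaling lost other islet hormone -0.28, and the mean of probes lost neutrophil 0.67 and Schwann 0.23. Leaving out pancreatectomy replicates 1 and 3 lost acinar 0.30, endothelial 0.059, matrix 0.16, fibroblast 0.080, immediate-early 0.24, inflammatory 0.19 and neutrophil 0.24. Quantile scaling without sham replicate 3 lost lymphocyte 0.60, neutrophil 0.099, other islet hormone -0.33 and Schwann 0.28. With normexp Bub1 (1.69), Dtl (1.79), Cdc6 (1.44), Aspm (1.73), Iqgap3 (1.68), Kcnh5 (-0.66), Pdzrn4 (-0.60), Nxph1 (-0.37), Mapk15 (-0.68), Aurka (1.82) and Kcnj11 (-0.74) lost their calls. Quantile scaling lost Top2a (4.59), Cdc6 (3.93), Cdk1 (4.46) and Aurka (2.14), and without sham replicate 3 it lost Cdk1 (3.74), Tk1 (3.42), Cdc6 (3.26), Pbk (3.69), Aspm (4.13), Iqgap3 (4.16), Aurka (2.28), Tbx1 (-2.85), Mapk15 (-1.04) and T2 (-1.05). Median scaling lost Aurka (2.01), an intensity trend lost Cdk1 (4.43) and Nxph1 (-1.16), and the mean of probes lost Kcnj11 (-0.59) and Pdzrn4 (-1.42). No scaling lost Neurog3 (-2.12), Tbx1 (-2.95), Cdc6 (3.53), Tk1 (3.78), Shcbp1 (3.95), Pbk (4.01), Top2a (4.18), Cdk1 (4.43), Aurka (2.13), Kcnj11 and 7 other named falls, and no filter on dim probes lost Tbx1, Tk1, Shcbp1, Pbk, Iqgap3, Cdk1, Aurka, Kcnj11 and 7 other named falls, with no change of value. With the row block Tk1 (3.78), Cdk1 (4.43), Aurka (2.13), Kcnj11 (-0.83), Gfra3 (-1.18), Nxph1 (-1.16) and Mapk15 (-0.99) lost theirs. Array weights gained calls for Irx1 (-1.64), Irx2 (-1.26), Foxm1 (2.00), Cish (1.22), Mt1 (-0.59), Mt2 (-0.77), Aldh1a3 (1.46), Lcn2 (3.11), Pcx (-0.57), Pdx1 (-0.48), Plaur (1.96), Reg3a (2.85), Reg3g (3.41), Slc2a2 (-0.82) and Vim (1.97). List calls were gained for the unfolded protein response with normexp 0.19, no filter 0.17, the stricter filter 0.17, quantile scaling 0.20, quantile without sham replicate 3 0.23 and without pancreatectomy replicates 1 and 3 0.37. They were gained for G1 cyclins with normexp 0.050 and no filter 0.14, for prolactin and serotonin with no filter 0.22, median scaling 0.0037 and quantile without sham replicate 3 0.30, and for hypoxia with the stricter filter -0.26.

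List medians that turned sign were endocrine progenitor -0.086 with the stricter filter, oxidative phosphorylation 0.0070 and ribosomal 0.056 with array weights, G1 cyclin -0.040, interferon -0.080 and p53 targets -0.056 with median scaling, and interferon -0.023, oxidative phosphorylation 0.031 and ribosomal 0.0066 with quantile scaling. Without pancreatectomy replicates 1 and 3 they were antioxidant 0.037, beta-cell disallowed -0.028, cholesterol 0.028, duct -0.094, endocrine progenitor -0.049, growth factor -0.048, interferon -0.17, lymphocyte -0.045, macrophage -0.23, oxidative phosphorylation 0.12 and ribosomal 0.045, with macrophage and interferon called lower. With quantile scaling and no sham replicate 3 they were acinar -0.26, cholesterol 0.0085, glycolysis 0.0078, oxidative phosphorylation 0.11, called higher, and ribosomal 0.036.

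Leaving out 1 array in turn gave medians of 0.52 to 1.59 for matrix, -0.24 to 0.66 for acinar, -0.15 to 0.046 for antioxidant, -0.11 to 0.0027 for cholesterol, 0.12 to 0.21 for endothelial, 0.048 to 0.14 for G1 cyclin, -0.18 to 0.025 for glycolysis, 0.17 to 0.41 for growth factor and -0.27 to -0.077 for heat shock lists. It gave -0.13 to 0.17 for interferon, 0.19 to 1.04 for lymphocyte, 0.21 to 0.91 for macrophage, 0.15 to 0.89 for neutrophil, -0.42 to -0.15 for other islet hormone, -0.11 to 0.12 for oxidative phosphorylation and -0.021 to 0.18 for p53 lists. It gave 0.049 to 0.38 for prolactin and serotonin, -0.075 to 0.053 for ribosomal, 0.13 to 0.42 for Schwann and 0.099 to 0.26 for unfolded protein lists. It gave 0.026 to 0.25 for duct, 0.026 to 0.31 for endocrine progenitor, -0.18 to -0.0099 for insulin and IGF and -0.25 to -0.12 for hypoxia lists. Without sham replicate 3 the medians of the acinar (-0.24), antioxidant (0.046), glycolysis (0.025), oxidative phosphorylation (0.12) and ribosomal (0.053, called higher) lists turned sign. Calls were gained for the unfolded protein list without sham replicate 3 (0.24) or pancreatectomy replicate 3 (0.26), prolactin and serotonin without the same arrays (0.38 and 0.19), G1 cyclins without pancreatectomy replicate 2 (0.048) and heat shock without sham replicate 2 (-0.27).

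Genes that turned sign had not passed the threshold with all arrays. Cpa1 was -0.092 with array weights, -0.067 without pancreatectomy replicates 1 and 3, -0.47 with quantile scaling and no sham replicate 3, -0.16 without the 4 arrays and -0.081 with median scaling. Ins1 was 0.087 with array weights, 0.20 without replicates 1 and 3 and 0.28 without the 4 arrays. Ins2 was 0.057, 0.17 and 0.20 in these, 0.24 with quantile scaling and no sham replicate 3 and 0.098 with quantile scaling. Irs2 was 0.0073 with array weights, 0.16 with quantile scaling and no sham replicate 3 and 0.47 without the 4 arrays. Tpx2 was 1.78 as the mean of its probes and 0.096 without the 4 arrays. Without the 4 arrays Bmp2 was -0.045 and Cldn5 -0.36. Leaving out 1 array gave -0.44 to 0.44 for Cpa1, -0.27 to 0.24 for Ins1, -0.36 to 0.23 for Ins2 and -0.38 to 0.16 for Irs2.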

Other observations

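The gene families named here, the test of list means, and the tests on single marker lists, on pancreatectomy replicates 2 and 4, on lymphocyte markers in replicates 1 and 2, on dilution by other RNA and on liver, gut and lymphoid RNA were chosen only after results were seen. Among called genes with a symbol, 106 of 151 were in no fixed list, 92 higher and 14 lower, and the genes in this paragraph and the next were picked from them. The families hold fixed list members too, which make up 2 of the 8 Cenp, 5 of the 6 Mcm and 2 of the 4 kinesin genes that rose. By gene name, 8 of 19 measured centromere genes (Cenp) rose, with a median change of 1.60 over the family. Of the minichromosome maintenance genes (Mcm), which include the subunits of the replicative helicase, 6 of 9 rose, with a median of 1.17. Of the Fanconi anaemia genes 2 of 8 rose (Fanca by 3.68 ± 0.49 and Fanci by 3.28 ± 0.38), as did the exonuclease Exo1 by 2.95 ± 0.30 and the polymerase Polq by 2.14 ± 0.35 (limma adjusted p from 0.0073 to 0.0371 for these genes). Of the kinesins 4 of 38 rose (Kif20a, Kif20b, Kif23 and Kifc1), and the family's median was -0.12. The Fanconi family's median was -0.027, and no median of these 4 families turned sign with quantile scaling, while median and no scaling shift all features alike.

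Chromatin and nuclear envelope genes were not counted or tested as a list, and those given here were picked from called genes. Ezh2, a histone methyltransferase, rose by 1.35 ± 0.21, Hmgb2 by 1.76 ± 0.19, Lmnb1 by 1.28 ± 0.18 and Chaf1a, a histone chaperone subunit, by 2.07 ± 0.30. The microtubule regulator Stmn1 rose by 2.29 ± 0.29, Anxa10 by 2.76 ± 0.39 and Folr2 by 1.14 ± 0.20 (limma adjusted p at most 0.0490). With the list mean of each array as a single value, 5 of 34 lists reached the smallest exact permutation p that 4 arrays against 4 can give, 0.0286 (DNA replication, mitosis, G1 cyclins, erythroid cells and other islet hormone cells). After adjustment over 34 lists 0 passed, and each of the 5 had an adjusted p of 0.194.

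Of 35 splits of the 8 arrays into 4 and 4, only the real one gave as many genes (1 of 35, with 194 genes and 46 the highest other). When all splits count alike, this is under the share of 0.05 set beforehand against chance. It is also the smallest share this test can give, so chance is made less likely but not excluded for the number of genes. The 46 came from sham replicates 1, 2 and 3 with pancreatectomy replicate 2 against the rest, which are the arrays without and with liver, gut or B-cell transcripts, and point to a structure of the samples. The 18 splits that keep 2 arrays of each slide row in each group are too few for a share under 0.05 (the real one 194, the highest other 0). For the number of lists past the threshold, 7 gave at least the 19 of the real one, with 21 the highest other, and chance cannot be excluded. Slide column follows the groups, so a column effect and an effect of pancreatectomy cannot be told apart. Whether the arrays of a group come from separate animals is not stated.

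Without sham replicate 3, the dim array, 62.4% of all called genes passed in the same direction, more than the share set beforehand against that array. Without sham replicate 2 it was 33.0% and without pancreatectomy replicate 4 34.0%, so the share also falls where other arrays are removed. For the rise of the cell cycle genes, the median of the members was 2.44 without sham replicate 3 against 2.50. That array had list means of -0.15 and -0.18, within the range of the sham arrays, so its removal could hardly move the median. The rise was thus present without the dim array, and the median is no further test of it as the cause. With the acinar or the macrophage list mean as a covariate the median was 2.55 and 2.24 and 37 and 24 of 42 calls passed. Then 57 and 71 features moved with the covariate, and these means had r of 0.18 and 0.44 with the group. For the acinar list this argues against RNA that follows its markers as the whole cause. The macrophage mean varied with the fibroblast mean within groups (r of 0.92), and with the fibroblast mean 0 of 42 calls passed. The macrophage result thus cannot decide for macrophage markers apart from fibroblast markers. With the fibroblast mean, the endothelial mean or the mean of the 4 lists the median was 2.09, 2.29 and 2.17. In limma 0 of 42 calls passed there, though all 42 had an unadjusted p under 0.05. Mki67 went from 3.91 ± 0.35 to 3.55 ± 0.41, 3.75 ± 0.46 and 3.74 ± 0.44, a smaller change with a wider SE, as these means also differ by group (r of 0.59, 0.61 and 0.56). In limma 111, 0 and 0 features moved with the covariate (2746, 1418 and 3643 at an unadjusted p under 0.05). The endothelial mean, which moved the fewest, does not test RNA that follows its markers. The mean of the 4 lists moved about as many at an unadjusted p under 0.05 as the macrophage mean (3695), but with 0 calls kept it cannot decide. The median of the members was 2.22 in pancreatectomy replicates 2 and 4 against sham, where 0 of the 4 marker means lay above the highest sham array. It was 2.52 in replicates 1 and 2, where the lymphocyte mean (0.14 and -0.16) did not lie above the highest sham one (0.19). It was 2.13 in the arrays without liver transcripts (pancreatectomy replicates 2 and 3, sham replicates 1, 2 and 3) and 2.56 in those without B-cell transcripts. The rise was thus present on arrays without each of these signals, so none of them, taken alone, accounts for it on those arrays. Both list means lay above every sham array on each pancreatectomy array, so any choice of arrays would show a rise, and these subsets are no further test. RNA that follows erythroid markers, which lay above every sham array on all 4 (lowest 0.48 against 0.45), stays open. So does RNA that follows macrophage, fibroblast or endothelial markers on replicates 1 and 3. Schwann markers stay open too, which were at -0.11 on replicate 3 (highest sham 0.13) and higher than sham on the others. The same is true of neutrophil markers, which were at 0.17 on replicate 2 (highest sham 0.30) and higher than sham on the others. Division of islet cells stays open as a hypothesis.

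The lower level of Neurog3 may reflect the mix of cells or regulation within cells. The beta-cell identity genes had a median of -0.37 against -2.11 for Neurog3. The SE of that median, 0.065, came from resampling its 22 genes as if independent, so it does not measure the spread between arrays. The identity list means were -0.60 to -0.11 on the pancreatectomy arrays relative to sham, which argues against dilution of all endocrine RNA as the whole cause. Neurog3 differed by -1.81 in the arrays without liver transcripts (SE 0.32) and by -2.26 (SE 0.27) in those without B-cell transcripts. Both lie more than 2 SE below 0.5 times the change over all arrays, with SE scaled from the fit of all arrays. Neurog3 was at most 9.52 on pancreatectomy arrays and at least 11.0 on sham arrays, so any choice of arrays would show a fall. The values thus show only that the fall was present on arrays without liver and on arrays without B-cell transcripts. Fewer cells that hold Neurog3 and less Neurog3 per cell cannot be told apart in whole islets, and a change of transcription after pancreatectomy stays open as an untested biological explanation.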
